A study of Mus musculus with 52 samples.

How the data were processed

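Brain was flash-frozen, RNA was extracted with Trizol, and Illumina TruSeq libraries were made from 1 ug of total RNA, per the labels' protocols. The cultured astrocytes carry the same text, and how their RNA was extracted is not given in the sources used here. HISAT2, StringTie, RSEM and the mm10 build are named, without versions or roles, per the submitters' processing notes. For the first KA cohort, the CNO set and the astrocytes the authors deposited TPM values per gene, a unit read here from the values, which total 978422 to 995304 per library. For the second KA cohort the authors deposited whole-number counts and TPM per gene, and the counts were tested as deposited. The tables held 55487, 55487, 53700 and 34042 genes for the first cohort, the CNO set, the astrocytes and the second cohort. Tables were processed separately, and tests were made only within a table.

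Samples were grouped by their titles and characteristics, and the columns of each table were matched to samples by name. No libraries within a group looked deposited more than once: the chi-square per degree of freedom between count libraries of a group was 57.2 to 109.

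TPM values were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean-variance trend, for genes at 1 TPM or more in at least 3 libraries. Counts were tested with edgeR 4.0.16 by its quasi-likelihood test, with TMM normalization and edgeR's own filter on low counts. The second cohort and the astrocytes were each fitted with all their groups, which share an estimate of spread. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and 0.05 was the threshold. Fold changes of counts are edgeR's own, and levels of those genes are shown in TPM. Interaction terms compared a treatment's change between genotypes. Gene lists written before the data were examined were tested with camera, with a preset correlation of 0.01 and again with an estimated one. P-values of lists were adjusted over 37 lists in brain and 36 in astrocytes.

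Genes to name were set by a rule written before the data were examined. It takes Apoe, Adora2a, Gfap and Plin2 always. It takes the 8 largest rises and 8 largest falls past the threshold, per comparison, with a mean log2 level over both groups above the median of tested genes, no overlap between the groups' libraries, and a symbol that is not a predicted gene (Gm with digits, ending in Rik or starting with LOC), a pseudogene, a Y-linked gene or Xist, or all such genes where there are fewer. It takes up to 4 members with the smallest p per list described. Some of the genes it takes are not reported here. The criterion of no overlap was not applied to interaction terms. Coordinates are from GENCODE M21 on mm10, and 30974 of 33931 matched genes (91.3%) had the same coordinates in the count table, with 111 of its 34042 identifiers not matched.

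Replicate numbers in the labels pair the libraries of the CNO set, where libraries of the same number deviated together (correlations of 0.119 to 0.244, 3 of 3 best with their own number), and the labels name no shared animal, litter or day. Alternatives set before the data were examined were median-ratio scaling or DESeq2 1.42.0 size factors, a pseudocount of 0.1, no filter on low values, a 2-fold threshold, a block by replicate number, a fit of only the groups compared, the DESeq2 Wald test, lists of at most 100 in place of 500 genes, and leaving out each library.

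The procedures were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. In the first KA comparison (14995 genes), 22 of the 2-fold and 61 of the 4-fold genes were recovered with 6 unchanged genes called, in CNO (15386 genes) 83, 96 and 12, in the second KA comparison (21861 genes) 57, 84 and 14, in Apoe knockout with KA (21995 genes) 53, 81 and 6, in medium from neurons on wild-type astrocytes (15667 genes) 92, 99 and 14, and in palmitic acid on knockout astrocytes (15692 genes) 89, 97 and 13.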

Results

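RNA was sequenced from 27 cultured astrocyte libraries and 25 brain libraries of C57BL/6 mice, to compare epileptic with untreated brain and lipid-treated with untreated astrocytes, with and without Apoe, which encodes the lipid carrier apolipoprotein E. Astrocytes, glial cells that feed and buffer neurons, made 9 groups of 3 libraries. Wild-type astrocytes were untreated or given medium from neurons, medium from Apoe knockout neurons, oleic acid or palmitic acid, and Apoe knockout astrocytes were untreated or given medium from neurons, oleic acid or palmitic acid. Brain came from a first cohort of the KA-induced epilepsy model (3 KA and 3 untreated libraries), a CNO-induced model (3 CNO and 3 untreated) and a second KA cohort (3 untreated, 4 KA, 3 Apoe knockout with KA and 3 labelled A2aR knockdown with KA). The brain region, doses and treatment times are not given in the sources used here. The titles of libraries given medium from either kind of neuron carry KA, so whether those neurons had been given KA is not known, and those of untreated knockout 3 and knockout palmitic acid 3 carry mix, which is not explained. The second cohort had 68760648 to 76643829 counts per library, and the depth of the other tables, in TPM, is unknown. Levels are mean ± SD in TPM over the libraries of a group, and log2 fold changes of single genes ± SE. The labels do not say that libraries came from separate animals or cultures, so p-values measure the spread between libraries, which may be technical. Fold changes from the TPM tables are on the log2(TPM + 1) scale, which understates the change of low genes. In the GENCODE M21 annotation of mm10, Apoe lies on chromosome 7, 19696109 to 19699188, Adora2a, the A2a adenosine receptor gene, on chromosome 10, 75316877 to 75334784, Gfap, an astrocyte intermediate filament, on chromosome 11, 102887336 to 102900912, and Plin2, which coats lipid droplets, on chromosome 4, 86648386 to 86670060.

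In the first KA cohort, interferon-induced genes were higher in KA than in untreated brain. Ifi27l2a, whose family can share its reads, stood at 161 ± 49.3 against 4.38 ± 1.1 TPM (n = 3 each, log2 4.88 ± 0.29, limma adjusted p = 0.00538). Cd52, a leukocyte surface protein, was at 119 ± 55 against 8.26 ± 2.14 TPM (log2 3.59 ± 0.40, limma adjusted p = 0.0346). Rasd1, a steroid-inducible small G protein, fell to 24.1 ± 2.95 from 61.8 ± 4.28 TPM (log2 -1.33 ± 0.16, limma adjusted p = 0.0462). Of 15331 genes, 24 were higher and 4 lower past limma's test. The lower ones were Rasd1 and the predicted genes Gm27905, Gm37385 and Gm48573, chosen after their values were seen. Also higher were Lgals3bp, Ifit3, Bst2, Xaf1, Rprm and Sparc (1.42 to 4.02 log2). Of 24 interferon response genes, 8 rose, 0 fell and 16 did not pass (24 and 0 adjusted over the list alone). Their median was 2.38 log2 (camera adjusted p = 3.46e-26, adjusted p = 0.371 with an estimated correlation), with Irf7 at 3.81 and Irf9 at 2.44. Of 20 markers of microglia, the immune cells of the brain, 0 passed limma's test, 20 had an unadjusted p under 0.05, and 20 were higher and 0 lower adjusted over the list alone. Their median was 1.81 log2 (camera adjusted p = 1.92e-15, adjusted p = 0.371 with an estimated correlation), with Ctss at 2.67 and C1qc at 2.19. Of 12 pan-reactive astrocyte genes, 0 passed limma's test, 12 had an unadjusted p under 0.05, and 12 were higher and 0 lower adjusted over the list alone. Their median was 1.87 log2 (camera adjusted p = 8.2e-09, adjusted p = 0.371 with an estimated correlation), with Cxcl10 at 4.34 and Cd44 at 2.08. Gfap was at 1445 ± 699 against 284 ± 55 TPM (log2 2.21 ± 0.43, limma adjusted p = 0.0902). Of 22 immediate early genes, which neuronal activity induces, 0 passed limma's test, 8 had an unadjusted p under 0.05, and 0 were higher and 7 lower adjusted over the list alone. Their median was -0.38 log2 (camera adjusted p = 9.78e-10, adjusted p = 0.371 with an estimated correlation), with Junb at -0.74 and Egr4 at -1.28. Of 13 markers of choroid plexus and ependyma, 0 passed limma's test, 9 had an unadjusted p under 0.05, and 9 were higher and 0 lower adjusted over the list alone. Their median was 1.33 log2 (camera adjusted p = 2.2e-05, adjusted p = 0.379 with an estimated correlation), with Otx2 at 2.03 and Aqp1 at 1.33. Apoe was at 9295 ± 3058 against 4602 ± 1380.5 TPM, Plin2 at 14.2 ± 4.82 against 5.93 ± 1.22 TPM and Adora2a at 3.13 ± 1.18 against 1.87 ± 0.306 TPM, none past limma's test (adjusted p = 0.269, 0.181 and 0.498). Untreated 3 stood apart from the other untreated libraries, with 9.01% of TPM from mitochondrial genes against 16.2% and 15.9%. With median-ratio scaling, which moved the median log2 fold change of all genes from 0.25 to -0.02, 24 were higher and 8 lower. The calls numbered 1 without untreated 1, 0 without untreated 2 (1929 at an unadjusted p under 0.05 by limma), 352 without untreated 3, 0 without KA 1 (1046) or KA 2 (883) and 136 without KA 3. They numbered 2 without a filter on low values, 44 with a pseudocount of 0.1 and 91 with the length trend removed. For Cd52, KA versus untreated brain, first cohort, gave log2 fold changes of 3.43, 3.58, 3.44 and 3.29 that did not pass without untreated 1, untreated 2, KA 1 or KA 2.

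In the CNO-induced model, genes of reactive astrocytes and microglia were higher than in untreated brain. Gfap stood at 2423 ± 243 against 293 ± 29.7 TPM (n = 3 each, log2 3.04 ± 0.11, limma adjusted p = 9.24e-05), Vim, another intermediate filament, at 392 ± 63.9 against 54.5 ± 4.35 TPM, and Serpina3n, a protease inhibitor, at 408 ± 72.1 against 32.2 ± 6.58 TPM (log2 3.63 ± 0.18, limma adjusted p = 0.000216). Plin2 rose to 13.2 ± 1.6 from 7.07 ± 0.0854 TPM (log2 0.81 ± 0.13, limma adjusted p = 0.0154). Ptgds, a prostaglandin D synthase, fell to 923 ± 293 from 2516 ± 320.0 TPM (log2 -1.49 ± 0.21, limma adjusted p = 0.0119). Of 15453 genes, 535 were higher and 36 lower past limma's test, and 764 and 164 with the replicate number as a block. Also higher were S100a4, Ifi27l2a, S100a6, Isg15 and Cd52 (2.88 to 3.68 log2), and lower Rasd1, Rpp25, Lmo1, Pnck, Cxcl12, Tshz2 and AW047730 (-0.62 to -0.84 log2). Of 12 pan-reactive astrocyte genes, 10 rose, 0 fell and 2 did not pass (11 and 0 adjusted over the list alone). Their median was 2.54 log2 (camera adjusted p = 3.21e-16, adjusted p = 0.237 with an estimated correlation), with Timp1 at 5.30 and Vim at 2.81. Of 20 microglial markers, 19 rose, 0 fell and 1 did not pass (20 and 0 adjusted over the list alone). Their median was 1.36 log2 (camera adjusted p = 3.02e-26, adjusted p = 0.237 with an estimated correlation), with Tyrobp at 1.36 and Laptm5 at 1.38. Of 24 interferon response genes, 11 rose, 0 fell and 13 did not pass (24 and 0 adjusted over the list alone). Their median was 1.54 log2 (camera adjusted p = 1.88e-15, adjusted p = 0.417 with an estimated correlation), with Bst2 at 2.60 and Oasl2 at 2.53. Of 26 cell cycle genes, 15 rose, 0 fell and 11 did not pass (22 and 0 adjusted over the list alone). Their median was 0.94 log2 (camera adjusted p = 4.56e-19, adjusted p = 0.237 with an estimated correlation), with Cdk1 at 2.03 and Ube2c at 2.24. Of 25 cholesterol synthesis genes, 4 rose, 0 fell and 21 did not pass (16 and 0 adjusted over the list alone). Their median was 0.41 log2 (camera adjusted p = 1.41e-08, adjusted p = 0.361 with an estimated correlation), with Nsdhl at 0.64 and Sqle at 0.60, and Mvd and Fdps rose too. Of 10 markers of dentate granule neurons, 0 rose, 2 fell and 8 did not pass (0 and 7 adjusted over the list alone). Their median was -0.59 log2 (camera adjusted p = 1.93e-06, adjusted p = 0.237 with an estimated correlation), with Stxbp6 at -0.58 and Plk5 at -1.05, the pair that fell. Apoe was at 3679.6 ± 554 against 4421 ± 291 TPM and Adora2a at 4.53 ± 2.01 against 1.72 ± 0.372 TPM, neither past limma's test (adjusted p = 0.34 and 0.134). The calls numbered 340, 317 and 215 without untreated 1, 2 or 3, 170 and 167 without CNO 2 or 3, and 197 without a filter on low values. For Plin2, CNO versus untreated brain gave log2 fold changes of 0.82, 0.75 and 0.78 that did not pass without untreated 3, CNO 2 or CNO 3.

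**Figure D1:**
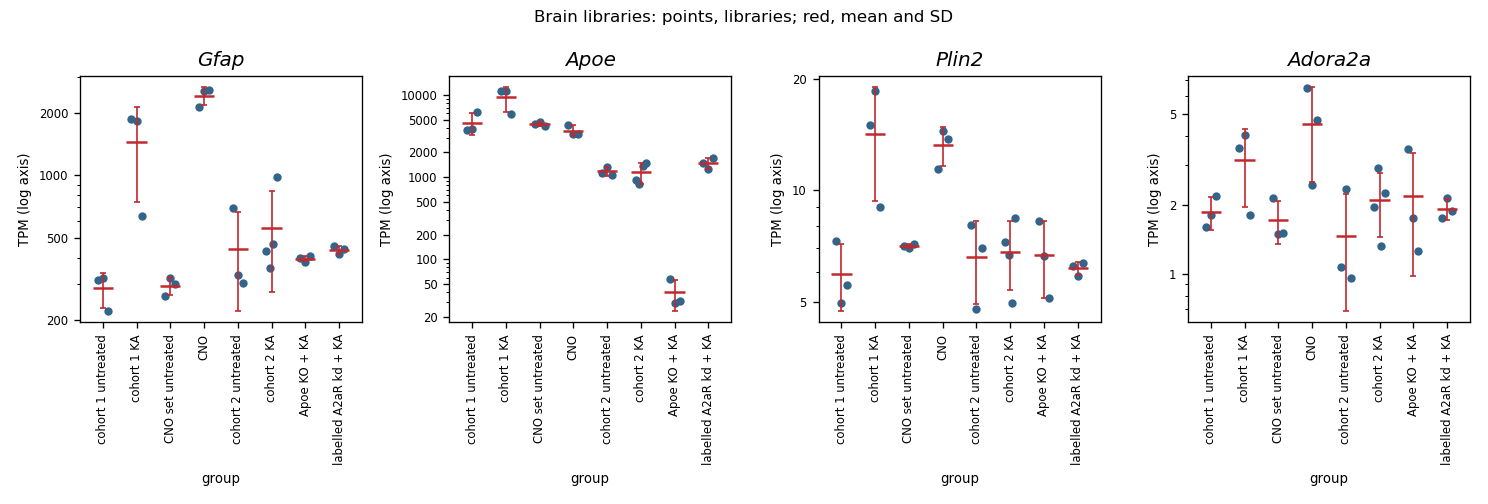
Gfap, Apoe, Plin2 and Adora2a in brain libraries, in TPM on log axes, by group, with a point per library and the mean and SD in red. Gfap lies higher in the CNO libraries than in their untreated libraries, and Apoe lies lowest in the Apoe knockout libraries.

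The genes higher in the first KA cohort were followed in the other brain tables, which share no library with it. In the CNO model the 23 measured had a median log2 fold change of 1.76 (limma's camera adjusted p = 5.9e-11 over 5 tests, adjusted p = 0.086 with an estimated correlation), and 223 from the calls without untreated 3 one of 0.49 (adjusted p = 2.29e-15). In the second KA cohort the median was 0.34 (adjusted p = 0.0292, adjusted p = 0.0762 with an estimated correlation), and -0.02 for 224 genes from the calls without that library (adjusted p = 0.191). In Apoe knockout with KA it was -0.34 (adjusted p = 0.0292, adjusted p = 0.0762 with an estimated correlation), and 0 for the 224 genes, with the test's direction down (adjusted p = 0.467). In the libraries labelled A2aR knockdown it was -0.15 (adjusted p = 0.156, adjusted p = 0.166 with an estimated correlation), and -0.11 for the 224 genes (adjusted p = 0.0295). The same 4 KA libraries are the treated group in the second KA comparison and the reference in the other two, so chance values in them enter these medians with opposite signs, which was checked after the values were seen. In 100 draws of simulated unchanged groups, with genes independent, medians ranged from -0.24 to 0.25 in second-cohort KA, -0.26 to 0.30 in Apoe knockout with KA (opposite in sign to KA in 62 draws) and -0.26 to 0.25 in the libraries labelled A2aR knockdown (in 58). Each of 6 pairs of KA libraries was used alone, still shared by the comparisons. Medians were 0.20 to 0.36, -0.49 to -0.18 and -0.24 to -0.08. The lower genes could be tested in CNO alone, with a median of 1.08 over 3 genes although the test's direction was down (adjusted p = 0.903), and of 0 over 122 genes from the calls without untreated 3, with direction down (adjusted p = 0.0295). Across genes, which are not independent replicates, log2 fold changes of the first cohort correlated with those of CNO at Pearson 0.406 and Spearman 0.24, with those of the second KA cohort at 0.056 and 0.042, of Apoe knockout with KA at -0.097 and -0.088, and of the libraries labelled A2aR knockdown at -0.138 and -0.224. In the first cohort and CNO, 14 genes were higher in both, against 0.792 for independent lists, and 0 in each second-cohort comparison.

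In the second KA cohort, Sgk1, Sik1 and Magi2 were lower in KA than in untreated brain. Sgk1, a glucocorticoid-inducible kinase, was at 58.9 ± 4.94 against 115 ± 4.23 TPM (n = 4 and 3, log2 -0.97 ± 0.07, edgeR adjusted p = 2.79e-05), Sik1, a salt-inducible kinase, at 3.41 ± 0.25 against 9.56 ± 1.83 TPM (log2 -1.44 ± 0.18, edgeR adjusted p = 0.0049) and Magi2, a synaptic scaffold, at 38.9 ± 6.35 against 49.1 ± 5.16 TPM (log2 -0.57 ± 0.08, edgeR adjusted p = 0.0144). Of 23318 genes, 6 were higher and 7 lower past edgeR's test, most of them sex-linked. Higher were Ddx3y, Eif2s3y, Kdm5d, Uty, Gm29650 and 3425401B19Rik, and lower, besides those 3 genes, Eif2s3x, Ddx3x, Xist and Gm27927, with the higher ones, Xist and Gm27927 chosen after their values were seen. Xist, expressed from the inactive X chromosome, was at 137 ± 13.6 TPM in untreated and 0.108 ± 0.111 TPM in KA libraries, and the Y-linked Ddx3y at 0.222 ± 0.158 and 28.6 ± 1.94 TPM, so sex and treatment cannot be told apart. Of 20 microglial markers, 0 passed edgeR's test, 10 had an unadjusted p under 0.05, 5 were higher and 0 lower by DESeq2, and 8 were higher and 0 lower adjusted over the list alone. Their median was 0.52 log2 (camera adjusted p = 1.3e-11, adjusted p = 0.212 with an estimated correlation), with Trem2 at 0.84 and Ctss at 0.77. Of 23 immediate early genes, 0 passed edgeR's test, 12 had an unadjusted p under 0.05, 0 were higher and 5 lower by DESeq2, and 0 were higher and 11 lower adjusted over the list alone. Their median was -0.59 log2 (camera adjusted p = 1.45e-08, adjusted p = 0.212 with an estimated correlation), with Fos at -1.95 and Egr2 at -3.25. Of 13 pan-reactive astrocyte genes, 0 passed edgeR's test, 4 had an unadjusted p under 0.05, 1 was higher and 0 lower by DESeq2, and 3 were higher and 0 lower adjusted over the list alone. Their median was 0.40 log2 (camera adjusted p = 0.000469, adjusted p = 0.212 with an estimated correlation), with Vim at 0.88 and Cd44 at 0.75. Of 26 cholesterol synthesis genes, 0 passed edgeR's test, 10 had an unadjusted p under 0.05, 0 were higher and 1 lower by DESeq2, and 0 were higher and 5 lower adjusted over the list alone. Their median was -0.27 log2 (camera adjusted p = 5.92e-08, adjusted p = 0.229 with an estimated correlation), with Stard4 at -0.59 and Insig1 at -0.36. Of 5 erythrocyte genes, 0 passed edgeR's test, 3 had an unadjusted p under 0.05, 0 were higher and 1 lower by DESeq2, and 0 were higher and 3 lower adjusted over the list alone. Their median was -0.80 log2 (camera adjusted p = 2.94e-05, adjusted p = 0.212 with an estimated correlation), with Hba-a1 at -0.80 and Hbb-bs at -0.55. Hba-a1 and its near-identical copy Hba-a2 can share reads. Gfap was at 558 ± 284 against 442 ± 220.2 TPM, Plin2 at 6.81 ± 1.43 against 6.6 ± 1.67 TPM, Apoe at 1152 ± 320.0 against 1174 ± 139.7 TPM and Adora2a at 2.11 ± 0.656 against 1.46 ± 0.773 TPM, none past edgeR's test (lowest adjusted p = 0.947). The calls numbered 20 without untreated 1, 155 with DESeq2 and, with X and Y genes left out, 4.

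Apoe knockout with KA was set against KA alone. Apoe was at 58.6, 29.7 and 31.2 TPM in the knockout libraries and 926, 829.7, 1383 and 1467 TPM in the KA libraries (n = 3 and 4, log2 -5.08 ± 0.33, edgeR adjusted p = 2.86e-05). Lcn2 fell to 0.457 ± 0.373 from 19.5 ± 16.6 TPM (log2 -5.39 ± 0.73, edgeR adjusted p = 0.0103), and Col6a1, a collagen VI chain, to 11.1 ± 1.42 from 65 ± 19.6 TPM (log2 -2.56 ± 0.42, edgeR adjusted p = 0.0432). Rprd1b rose to 16 ± 1.22 from 5.58 ± 0.935 TPM (log2 2.08 ± 0.15, edgeR adjusted p = 3.49e-05). Of 23318 genes, 7 were higher and 19 lower past edgeR's test. Also higher were Kirrel2, Zkscan3, Abcb10 and Trib2 (0.59 to 1.66 log2), and lower Nudt19, Sbsn, Gpatch1 and Kmt2e (-0.59 to -1.27 log2). Besides Apoe, 7 of the calls lay within 20 Mb of it on chromosome 7, among them Nudt19 (chromosome 7, 35547185 to 35556304), Kirrel2, Sbsn and Gpatch1. Of 13 pan-reactive astrocyte genes, 0 rose, 1 fell and 12 did not pass (0 and 4 adjusted over the list alone). Their median was -0.72 log2 (camera adjusted p = 2.04e-05, adjusted p = 0.0742 with an estimated correlation), with Lcn2 at -5.39 and Osmr at -0.99, Lcn2 being the call. Of 18 markers of mural cells and fibroblasts, 0 passed edgeR's test, 11 had an unadjusted p under 0.05, 3 were higher and 0 lower by DESeq2, and 9 were higher and 0 lower adjusted over the list alone. Their median was 0.57 log2 (camera adjusted p = 1.23e-08, adjusted p = 0.0742 with an estimated correlation), with Tagln at 0.96 and Acta2 at 0.76. Of 26 cholesterol synthesis genes, 0 passed edgeR's test, 10 had an unadjusted p under 0.05, 1 was higher and 0 lower by DESeq2, and 0 were higher and 0 lower adjusted over the list alone. Their median was 0.23 log2 (camera adjusted p = 1.5e-06, adjusted p = 0.274 with an estimated correlation), with Stard4 at 0.61 and Pmvk at 0.35. Of 20 microglial markers, 0 passed edgeR's test, 7 had an unadjusted p under 0.05, 0 were higher and 0 lower by DESeq2, and 0 were higher and 0 lower adjusted over the list alone. Their median was -0.29 log2 (camera adjusted p = 0.00208, adjusted p = 0.454 with an estimated correlation), with Ctss at -0.53 and Tyrobp at -0.59. Gfap was at 395 ± 11.6 against 558 ± 284 TPM and Plin2 at 6.68 ± 1.58 against 6.81 ± 1.43 TPM, neither past edgeR's test (adjusted p = 0.731 and 1). The calls numbered 16, 15 and 15 without knockout 1, 2 or 3, 327 with DESeq2 and 11, of which 10 were shared, with only the groups compared in the fit. For Lcn2, Apoe knockout with KA versus KA brain gave log2 fold changes of -4.96 and -5.46 that did not pass without knockout 1 or 2.

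The libraries labelled A2aR knockdown with KA were set against KA alone. Adora2a, the targeted gene, was at 1.75, 2.15 and 1.89 TPM in the labelled libraries and 1.95, 2.9, 1.32 and 2.26 TPM in the KA libraries (n = 3 and 4, log2 0.13 ± 0.39, edgeR adjusted p = 0.963), so a knockdown was not measurable in its RNA. In the libraries labelled A2aR knockdown, Wfs1, an endoplasmic reticulum protein, was higher at 94.3 ± 16.5 against 46.8 ± 8.63 TPM (log2 1.10 ± 0.15, edgeR adjusted p = 0.0185), as were Gng4, a G protein subunit, at 23.9 ± 1.64 against 13.4 ± 2.3 TPM and Hba-a1, an alpha globin, at 169 ± 24.3 against 89.1 ± 12.8 TPM (log2 1.00 ± 0.13, edgeR adjusted p = 0.0181). Ice2 was lower at 4.02 ± 0.148 against 7.7 ± 1.05 TPM (log2 -1.10 ± 0.14, edgeR adjusted p = 0.0127). Of 23318 genes, 4 were higher and 5 lower past edgeR's test. The others were Magi2 (log2 fold change 0.71), higher, and Gpc2 and the immunoglobulin genes Ighg1, Ighg2b and Jchain, lower, chosen after their values were seen. Of 5 erythrocyte genes, 1 rose, 0 fell and 4 did not pass (5 and 0 adjusted over the list alone). Their median was 0.93 log2 (camera adjusted p = 1.06e-05, adjusted p = 0.134 with an estimated correlation), with Hba-a1 at 1.00 and Hba-a2 at 0.93, Hba-a1 being the call. Of 12 markers of inhibitory neurons, 0 passed edgeR's test, 7 had an unadjusted p under 0.05, 0 were higher and 0 lower by DESeq2, and 5 were higher and 0 lower adjusted over the list alone. Their median was 0.36 log2 (camera adjusted p = 9.3e-05, adjusted p = 0.0681 with an estimated correlation), with Lhx6 at 0.56 and Gad1 at 0.23. Of 23 immediate early genes, 0 passed edgeR's test, 12 had an unadjusted p under 0.05, 3 were higher and 0 lower by DESeq2, and 7 were higher and 0 lower adjusted over the list alone. Their median was 0.52 log2 (camera adjusted p = 1.06e-05, adjusted p = 0.409 with an estimated correlation), with Dusp6 at 0.69 and Junb at 0.74. Of 12 genes of adenosine signalling, 0 passed edgeR's test, 2 had an unadjusted p under 0.05, 0 were higher and 0 lower by DESeq2, and 0 were higher and 0 lower adjusted over the list alone. Their median was 0.01 log2 (camera adjusted p = 0.711, adjusted p = 0.875 with an estimated correlation), with Slc29a1 at -0.30 and Adora1 at 0.28. Apoe was at 1475 ± 220.2 against 1152 ± 320.0 TPM, Gfap at 437 ± 18.5 against 558 ± 284 TPM and Plin2 at 6.16 ± 0.247 against 6.81 ± 1.43 TPM, none past edgeR's test (adjusted p = 0.61, 0.876 and 0.956). The calls numbered 5 without KA 1, 5 without KA 3, 0 without labelled library 5 (2285 at an unadjusted p under 0.05 by edgeR) and 249 with DESeq2. With only the groups compared in the fit there was 1 call, and 0 of the 9 genes were shared. For Wfs1, A2aR knockdown with KA versus KA brain, by label, gave log2 fold changes of 1.03, 1.05, 1.11, 1.06 and 0.96 that did not pass without KA 2, KA 3, KA 4, labelled library 5 or labelled library 6.

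**Figure D2:**
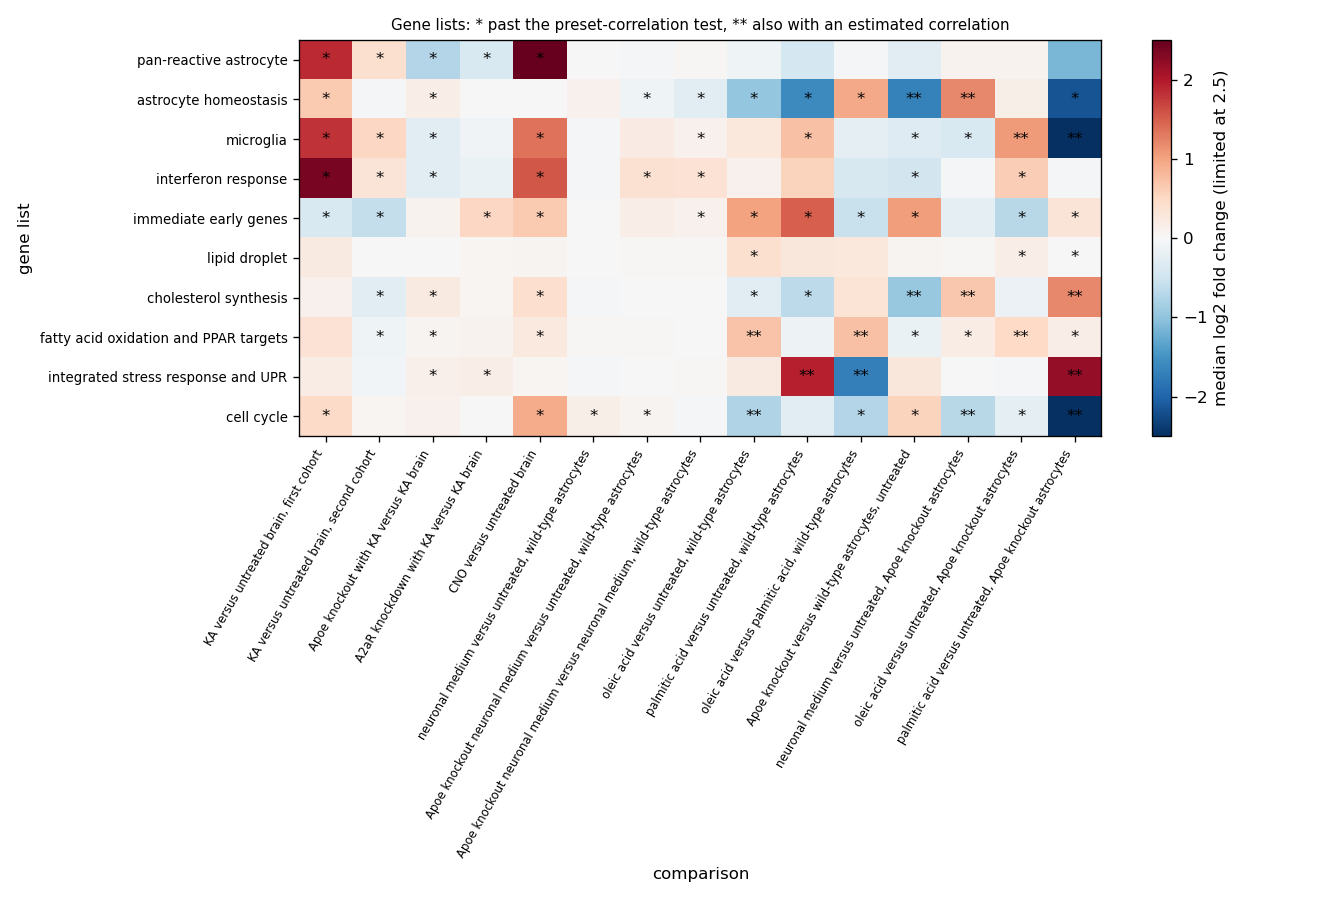
Median log2 fold change of 10 gene lists, by color and limited at 2.5, in each of 15 comparisons, with * where camera's test with a preset correlation passed and ** where it also passed with an estimated correlation. The pan-reactive astrocyte list in the CNO model has a median of 2.54, and the brain comparisons have no list marked **.

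Few genes differed in wild-type astrocytes given medium from neurons. Aldh1a1, which makes retinoic acid, fell to 302 ± 12.1 from 399 ± 11.8 TPM (n = 3 each, log2 -0.40 ± 0.07, limma adjusted p = 0.026), Tpm1, an actin-binding tropomyosin, fell to 1848 ± 54.1 from 2126 ± 50.04 TPM (log2 -0.20 ± 0.04, limma adjusted p = 0.0406), and Sap30l, of a histone deacetylase complex, rose to 32.9 ± 2.47 from 26.1 ± 0.88 TPM (log2 0.32 ± 0.05, limma adjusted p = 0.0238). Of 16161 genes, 3 were higher and 3 lower past limma's test, the others being Deup1, Mcidas and Rpl28-ps1 (log2 fold changes 0.75, 0.75 and -0.42), chosen after their values were seen. Of 22 genes of extracellular matrix and fibrosis, 0 passed limma's test, 7 had an unadjusted p under 0.05, and 0 were higher and 2 lower adjusted over the list alone. Their median was -0.15 log2 (camera adjusted p = 4.31e-07, adjusted p = 0.223 with an estimated correlation), with Mmp2 at -0.25 and Sparc at -0.11. Of 14 markers of mural cells and fibroblasts, 0 passed limma's test, 6 had an unadjusted p under 0.05, and 0 were higher and 4 lower adjusted over the list alone. Their median was -0.17 log2 (camera adjusted p = 3.23e-05, adjusted p = 0.0182 with an estimated correlation), with Tagln at -0.26 and Col1a2 at -0.21. Of 28 cell cycle genes, 0 passed limma's test, 5 had an unadjusted p under 0.05, and 0 were higher and 0 lower adjusted over the list alone. Their median was 0.14 log2 (camera adjusted p = 1.08e-06, adjusted p = 0.155 with an estimated correlation), with Ccnb2 at 0.16 and Kif20a at 0.16. Gfap was at 1311 ± 93.4 against 1169.7 ± 78 TPM, Plin2 at 79.1 ± 4.54 against 84.3 ± 2.95 TPM, Apoe at 4588 ± 431 against 4682 ± 405 TPM and Adora2a at 0.307 ± 0.195 against 0.323 ± 0.231 TPM, none past limma's test (lowest adjusted p = 0.78). The calls numbered 1, 0 and 3 without untreated 1, 2 or 3 and 0, 11 and 0 without treated 1, 2 or 3, with 864, 758 and 979 at an unadjusted p under 0.05 by limma where it was 0. They numbered 30 without a filter on low values, 3 with a pseudocount of 0.1, 2 with median-ratio scaling and 1, with 0 of the 6 genes shared, with only the groups compared in the fit.

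Adgre1 and Cd52 were higher in wild-type astrocyte cultures given medium from Apoe knockout neurons than in untreated ones. Adgre1, the macrophage marker F4/80, stood at 56.7 ± 2.75 against 10.1 ± 1.7 TPM (n = 3 each, log2 2.38 ± 0.22, limma adjusted p = 4.58e-06), and Cd52 at 114 ± 16.4 against 22.8 ± 4.66 TPM (log2 2.27 ± 0.24, limma adjusted p = 1.88e-05). Eln, elastin, fell to 55.7 ± 2.29 from 91.8 ± 5.98 TPM (log2 -0.71 ± 0.10, limma adjusted p = 0.000209). Of 16161 genes, 157 were higher and 86 lower past limma's test, and 77 and 82 with median-ratio scaling. Also higher were Cd72, Slc13a3, Egr1, Glipr1, Coro1a and Arhgdib (1.06 to 1.73 log2), and lower Fam107a, Pcp4, Lsp1, Hspb6, Phyhd1 and Nppc (-0.60 to -0.90 log2). Of 18 genes of activated phagocytes, 3 rose, 4 fell and 11 did not pass (3 and 7 adjusted over the list alone). Their median was -0.08 log2 (camera adjusted p = 0.00188, adjusted p = 0.031 with an estimated correlation). The median and test were down, and the mean was 0.07. Ccl3, Ccl4 and Ms4a7 rose and Fcgr3, Lgals3, Gpnmb and Fcgr2b fell, with Ccl4, Ms4a7 and Fcgr2b chosen after their values were seen. Of 23 interferon response genes, 0 passed limma's test, 11 had an unadjusted p under 0.05, and 5 were higher and 0 lower adjusted over the list alone. Their median was 0.37 log2 (camera adjusted p = 9.8e-06, adjusted p = 0.429 with an estimated correlation), with Usp18 at 0.92 and Bst2 at 0.44. Of 8 oligodendrocyte and myelin genes, 0 rose, 1 fell and 7 did not pass (0 and 4 adjusted over the list alone). Their median was -0.35 log2 (camera adjusted p = 3.78e-05, adjusted p = 0.031 with an estimated correlation), with Cldn11 at -0.54 and Trf at -0.52, Cldn11 being the call. Gfap was at 1114 ± 51.5 against 1169.7 ± 78 TPM, Plin2 at 82 ± 3.34 against 84.3 ± 2.95 TPM and Apoe at 3930.2 ± 234 against 4682 ± 405 TPM, none past limma's test (lowest adjusted p = 0.258). The calls numbered 140, 154 and 138 without untreated 1, 2 or 3, and 117, 152 and 139 without treated 1, 2 or 3.

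Adgre1 and Lyz2 were higher with medium from Apoe knockout neurons when it was set directly against medium from neurons. Adgre1 was at 56.7 ± 2.75 against 9.04 ± 1.65 TPM (n = 3 each, log2 2.53 ± 0.22, limma adjusted p = 1.85e-06), and Lyz2, a lysozyme, at 347 ± 14.5 against 159 ± 19 TPM (log2 1.13 ± 0.17, limma adjusted p = 0.000664). Acsl6, which activates fatty acids, fell to 11.5 ± 0.64 from 19.3 ± 1.0 TPM (log2 -0.70 ± 0.13, limma adjusted p = 0.00451). Of 16161 genes, 156 were higher and 73 lower past limma's test. Also higher were Cd52, Cd72, Arhgdib, Slc13a3, C3ar1 and Glipr1 (0.97 to 2.33 log2), and lower Ednrb, Pcp4, Mmd2, Nppc, Itih5 and Ctxn3 (-0.51 to -0.64 log2). Of 19 microglial markers, 4 rose, 1 fell and 14 did not pass (9 and 2 adjusted over the list alone). Their median was 0.11 log2 (camera adjusted p = 0.0149, adjusted p = 0.345 with an estimated correlation), with Aif1 at 1.41, Laptm5 at 0.54 and Gpr34 at -1.18, and Fcrls and Cx3cr1, the latter chosen after its values were seen, rose too. Of 14 astrocyte homeostasis genes, 0 rose, 2 fell and 12 did not pass (0 and 3 adjusted over the list alone). Their median was -0.27 log2 (camera adjusted p = 1.27e-06, adjusted p = 0.208 with an estimated correlation), with Ntsr2 at -0.64, which fell. Of 23 interferon response genes, 2 rose, 0 fell and 21 did not pass (13 and 0 adjusted over the list alone). Their median was 0.35 log2 (camera adjusted p = 1.23e-08, adjusted p = 0.345 with an estimated correlation), with Bst2 at 0.64 and Irf9 at 0.45, the pair that rose. Gfap was at 1114 ± 51.5 against 1311 ± 93.4 TPM and Plin2 at 82 ± 3.34 against 79.1 ± 4.54 TPM, neither past limma's test (adjusted p = 0.176 and 0.787). The calls numbered 105 without neuronal medium 1, and 120, 140 and 138 without knockout medium 1, 2 or 3.

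Genes of fatty acid oxidation were higher in wild-type astrocytes with oleic acid, an unsaturated fatty acid. Plin2 rose to 183 ± 11.1 from 84.3 ± 2.95 TPM (n = 3 each, log2 1.11 ± 0.06, limma adjusted p = 9.44e-13), and Ucp2, a mitochondrial carrier, to 345 ± 33.7 from 22.2 ± 3.0 TPM (log2 3.90 ± 0.12, limma adjusted p = 1.23e-16). Eln fell to 1.68 ± 0.282 from 91.8 ± 5.98 TPM (log2 -5.12 ± 0.10, limma adjusted p = 1.3e-19). Gfap fell to 564 ± 27.3 from 1169.7 ± 78 TPM and Apoe to 3235 ± 189 from 4682 ± 405 TPM, while Adora2a rose to 1.64 ± 0.125 from 0.323 ± 0.231 TPM (limma adjusted p = 3.86e-10, 7.01e-05 and 2.27e-06). Of 16161 genes, 5050 were higher and 4619 lower past limma's test. Also higher were Wif1, Nr4a1, Medag, Rarres1, Il33, Junb and Ntn1 (3.20 to 5.87 log2), and lower Mfap4, Actg2, Col3a1, H19, Omd, Npr3 and Kcne1l (-3.13 to -4.50 log2). Of 26 genes of fatty acid oxidation and PPAR targets, 23 rose, 0 fell and 3 did not pass (24 and 0 adjusted over the list alone). Their median was 0.70 log2 (camera adjusted p = 3.49e-09, adjusted p = 0.0039 with an estimated correlation), with Acaa2 at 1.30 and Hadh at 0.75. Of 22 lipid droplet genes, 15 rose, 3 fell and 4 did not pass (15 and 3 adjusted over the list alone). Their median was 0.40 log2 (camera adjusted p = 0.00357, adjusted p = 0.115 with an estimated correlation), with Pnpla2 at 0.96 and Fitm2 at 0.77, and those that fell were G0s2, Mgll and Mogat2. Of 14 astrocyte homeostasis genes, 1 rose and 13 fell (1 and 13 adjusted over the list alone). Their median was -0.97 log2 (camera adjusted p = 1.86e-06, adjusted p = 0.115 with an estimated correlation), with Aldoc at -2.28 and Gja1 at -1.95, and the one that rose was Aldh1l1. G0s2, Mgll, Mogat2, Aldh1l1, Ddx3y and En2 were chosen after their values were seen. Of 28 cell cycle genes, 0 rose, 24 fell and 4 did not pass (0 and 24 adjusted over the list alone). Their median was -0.76 log2 (camera adjusted p = 2.86e-09, adjusted p = 0.0466 with an estimated correlation), with Ccna2 at -1.31 and Kif11 at -1.94. The Y-linked Ddx3y was at 1.05 ± 0.458 against 17.6 ± 2.33 TPM. En2, a midbrain and cerebellar transcription factor, was at 95.1 ± 3.46 against 1.03 ± 0.0208 TPM. Treatment and culture source cannot be told apart. Mitochondrial genes took 2.96% to 3.98% of TPM against 5.52% to 6.83%.

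Genes of the integrated stress response, cytokines and chemokines were higher in wild-type astrocytes given palmitic acid, a saturated fatty acid. Ddit3, the stress transcription factor CHOP, rose to 522 ± 15.3 from 39.6 ± 4.36 TPM (n = 3 each, log2 3.69 ± 0.08, limma adjusted p = 5.5e-19), Ccl2, a chemokine, to 151 ± 44.2 from 4.62 ± 1.22 TPM (log2 4.74 ± 0.66, limma adjusted p = 2.13e-06) and Plin2 to 327 ± 19 from 84.3 ± 2.95 TPM (log2 1.94 ± 0.06, limma adjusted p = 4.75e-17). Kcnj10, the potassium channel of astrocytes, fell to 8.66 ± 2.66 from 209 ± 10.2 TPM (log2 -4.48 ± 0.13, limma adjusted p = 6.52e-17), Gfap to 279 ± 40.4 from 1169.7 ± 78 TPM and Apoe to 2303 ± 138 from 4682 ± 405 TPM (limma adjusted p = 2.53e-15 and 6.53e-09). Of 16161 genes, 4325 were higher and 5343 lower past limma's test. Also higher were Mmp3, Fosl1, Rgs16, Trib3, Chac1, Hmga1 and Plaur (4.18 to 5.23 log2), and lower Col3a1, Aldoc, H19, Slco1a4, Igf2, Fndc1 and Slc39a12 (-3.33 to -4.22 log2). Of 23 genes of the integrated stress and unfolded protein responses, 20 rose, 1 fell and 2 did not pass (21 and 1 adjusted over the list alone). Their median was 1.94 log2 (camera adjusted p = 6.68e-14, adjusted p = 0.00127 with an estimated correlation), with Asns at 3.34 and Atf4 at 2.82, and the one that fell was Ddit4. Of 24 cytokine and chemokine genes, 18 rose, 2 fell and 4 did not pass (18 and 2 adjusted over the list alone). Their median was 1.60 log2 (camera adjusted p = 4.58e-05, adjusted p = 0.237 with an estimated correlation), with Lif at 2.60 and Tgfb1 at 1.70, and those that fell were Tgfb3 and Tgfb2. Ddit4 and Tgfb2 were chosen after their values were seen. Of 14 astrocyte homeostasis genes, 0 rose and 14 fell (0 and 14 adjusted over the list alone). Their median was -1.59 log2 (camera adjusted p = 7.17e-08, adjusted p = 0.0706 with an estimated correlation), with Glul at -1.46 and Mlc1 at -1.63. Of 22 lipid droplet genes, 10 rose, 7 fell and 5 did not pass (10 and 7 adjusted over the list alone). Their median was 0.29 log2 (camera adjusted p = 0.211, adjusted p = 0.523 with an estimated correlation), with Hilpda at 1.29 and Lpin1 at -1.37. Of 19 microglial markers 12 rose and 4 fell (12 and 4 adjusted over the list alone), with a median of 0.74 log2 (camera adjusted p = 0.00927, adjusted p = 0.181 with an estimated correlation). Of 18 activated phagocyte genes 15 rose and 2 fell (15 and 2 adjusted over the list alone), with a median of 1.60 log2 (camera adjusted p = 8.93e-07, adjusted p = 0.00127 with an estimated correlation). Adora2a was at 0.507 ± 0.0153 against 0.323 ± 0.231 TPM and did not pass limma's test (adjusted p = 0.219). Ddx3y was at 3.78 ± 0.649 against 17.6 and En2 at 7.14 ± 0.335 against 1.03 TPM, so treatment and source cannot be told apart. Mitochondrial genes took 3.48% to 4.17% of TPM.

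**Figure D3:**
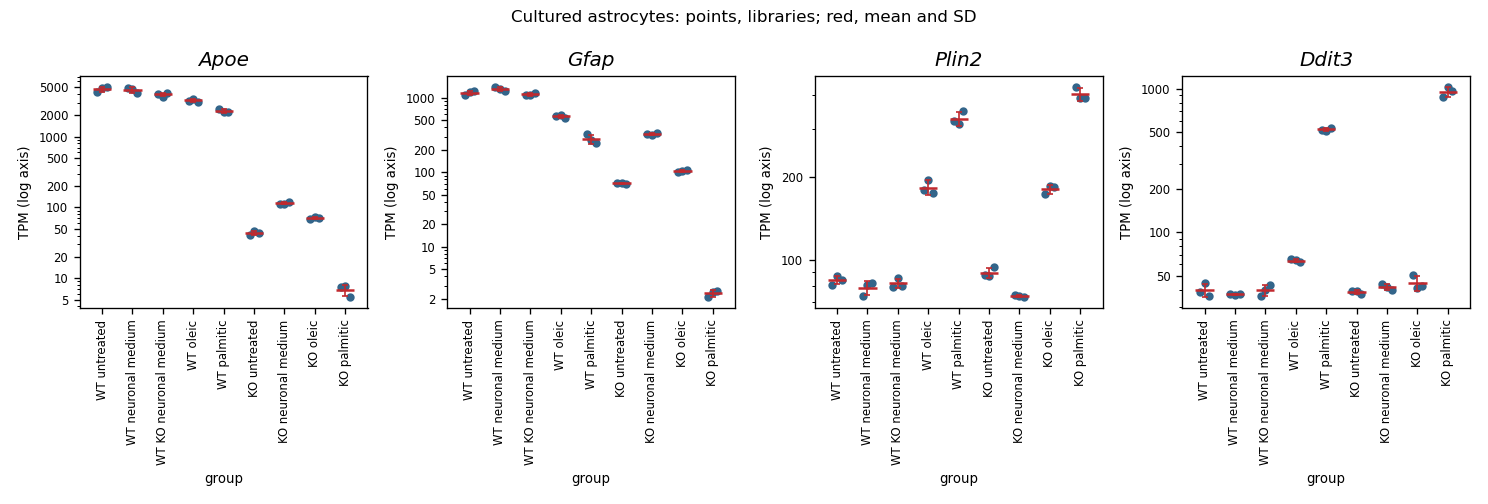
Apoe, Gfap, Plin2 and Ddit3 in cultured astrocytes, in TPM on log axes, by group, with a point per library and the mean and SD in red. Plin2 lies at 327 TPM with palmitic acid in wild-type and 401 TPM in Apoe knockout cultures, against 84.3 and 89.6 TPM untreated.

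Oleic and palmitic acid, which differ in saturation and chain length, were compared directly in wild-type astrocytes, at doses and times the labels do not give. Plin2 was lower with oleic acid, at 183 ± 11.1 against 327 ± 19 TPM (n = 3 each, log2 -0.83 ± 0.06, limma adjusted p = 5.32e-11, 95% interval -0.95 to -0.71), as were Ddit3 at 63.7 ± 1.67 against 522 ± 15.3 TPM (log2 -3.02 ± 0.08, limma adjusted p = 3.97e-17) and Ptgs2, the inducible cyclooxygenase, at 1.3 ± 0.35 against 104 ± 15.8 TPM (log2 -5.51 ± 0.23, limma adjusted p = 2.4e-14). Kcnj10 was higher with oleic acid, at 82.8 ± 5.92 against 8.66 ± 2.66 TPM, as were Gfap at 564 ± 27.3 against 279 ± 40.4 TPM, Apoe at 3235 ± 189 against 2303 ± 138 TPM and Adora2a at 1.64 ± 0.125 against 0.507 ± 0.0153 TPM (limma adjusted p = 3.02e-14, 3.57e-10, 0.000156 and 3.3e-05). Of 16161 genes, 5243 were higher and 4163 lower past limma's test with oleic acid. Also higher were Rarres1, Wif1, Lcat, Bicc1, Etfbkmt and Disp3 (2.70 to 3.84 log2), and lower Ccl2, Rgs16, Areg, Trib3, Hmga2, Gdf15 and Cth (-3.62 to -5.18 log2). Of 23 genes of the integrated stress and unfolded protein responses, 1 rose, 20 fell and 2 did not pass (1 and 20 adjusted over the list alone). Their median was -1.70 log2 (camera adjusted p = 7.24e-14, adjusted p = 0.00145 with an estimated correlation), with Asns at -2.91 and Atf4 at -2.11, and the one that rose was Ddit4. Of 26 genes of fatty acid oxidation and PPAR targets, 23 rose, 2 fell and 1 did not pass (23 and 2 adjusted over the list alone). Their median was 0.74 log2 (camera adjusted p = 5.92e-07, adjusted p = 0.015 with an estimated correlation), with Hadh at 1.04 and Acadvl at 0.96, and those that fell were Acot2 and Angptl4. Of 11 A2-type reactive astrocyte genes, 1 rose, 9 fell and 1 did not pass (1 and 9 adjusted over the list alone). Their median was -1.72 log2 (camera adjusted p = 1.16e-05, adjusted p = 0.0305 with an estimated correlation), with S100a10 at -1.72 and Clcf1 at -1.11, and the one that rose was Cd109. Of 22 lipid droplet genes, 11 rose, 5 fell and 6 did not pass (12 and 5 adjusted over the list alone). Their median was 0.27 log2 (camera adjusted p = 0.327, adjusted p = 0.697 with an estimated correlation), with Hsd17b11 at 1.18 and Lpin1 at 1.53, and with Plin2 the lower ones were G0s2, Gpat3, Hilpda and Mogat2. Ddit4, Acot2, Angptl4, Cd109, G0s2, Gpat3, Hilpda and Mogat2 were chosen after their values were seen. Lipid droplet genes whose difference did not pass limma's test, with 95% intervals, were Dgat2 -0.21 (-0.58 to 0.17), Gpat4 -0.09 (-0.21 to 0.04), Lipe 0.17 (-0.04 to 0.37), Lpin2 0.26 (0.02 to 0.50), Plin3 0.11 (-0.02 to 0.23) and Soat1 0.12 (-0.12 to 0.36). The interval of Lpin2 excludes 0, and its limma adjusted p was 0.0573. Ddx3y was at 1.05 against 3.78 and En2 at 95.1 against 7.14 TPM, so treatment and source cannot be told apart.

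Homeostasis genes were lower in untreated Apoe knockout than wild-type astrocytes. Apoe was at 40.4, 47.1 and 43.5 TPM in the knockout and 4234, 4787 and 5024 TPM in the wild-type libraries (log2 -6.71 ± 0.10, limma adjusted p = 5.75e-22). Gfap fell to 70.8 ± 0.648 from 1169.7 ± 78 TPM (n = 3 each, log2 -4.02 ± 0.08, limma adjusted p = 1.96e-19) and Kcnj10 to 14.1 ± 0.69 from 209 ± 10.2 TPM, while Il33, an alarmin cytokine, rose to 391 ± 2.41 from 5.23 ± 0.492 TPM (log2 5.98 ± 0.13, limma adjusted p = 7.05e-19). Of 16161 genes, 3855 were higher and 3403 lower past limma's test. Also higher were Wif1, Stc1, Mmp3, Col2a1, Fgf7, Medag and Rarres1 (3.84 to 5.79 log2), and lower Pla2g7, Eln, Mfap4, Col3a1 and Kcne1l (-3.62 to -4.14 log2). Of 14 homeostasis genes, 0 rose and 14 fell (0 and 14 adjusted over the list alone). Their median was -1.68 log2 (camera adjusted p = 1.07e-11, adjusted p = 0.0304 with an estimated correlation), with Aldoc at -3.10 and Mlc1 at -2.21. Of 26 cholesterol synthesis genes, 1 rose, 22 fell and 3 did not pass (1 and 22 adjusted over the list alone). Their median was -0.95 log2 (camera adjusted p = 9.73e-10, adjusted p = 0.019 with an estimated correlation), with Sqle at -1.36 and Nsdhl at -1.28, and the one that rose was Ebp, chosen after its values were seen. Of 9 markers of choroid plexus and ependyma, 0 rose and 9 fell (0 and 9 adjusted over the list alone). Their median was -1.80 log2 (camera adjusted p = 2.83e-07, adjusted p = 0.017 with an estimated correlation), with Rarres2 at -1.90 and Aqp1 at -1.80. Of 28 cell cycle genes, 22 rose, 0 fell and 6 did not pass (23 and 0 adjusted over the list alone). Their median was 0.56 log2 (camera adjusted p = 2.83e-07, adjusted p = 0.082 with an estimated correlation), with Ccnb2 at 0.80 and Mcm6 at 0.66. Plin2 was at 89.6 ± 3.71 against 84.3 ± 2.95 TPM and Adora2a at 0.533 ± 0.18 against 0.323 ± 0.231 TPM, neither past limma's test (adjusted p = 0.226 and 0.208). Ddx3y was at 32.3 ± 1.09 against 17.6 ± 2.33 and En2 at 111 ± 2.1 against 1.03 ± 0.0208 TPM. Genotype and culture source cannot be told apart.

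Homeostasis genes were higher in Apoe knockout astrocytes given medium from neurons. Apoe was at 113, 113 and 118 TPM in the treated and 40.4, 47.1 and 43.5 TPM in the untreated knockout libraries (log2 1.37 ± 0.10, limma adjusted p = 2.83e-10). Gfap rose to 325 ± 10.04 from 70.8 ± 0.648 TPM (n = 3 each, log2 2.18 ± 0.08, limma adjusted p = 1.22e-14) and Kcnj10 to 81.6 ± 3.34 from 14.1 ± 0.69 TPM, while Mmp3, a matrix protease, fell to 5.14 ± 0.31 from 92.5 ± 1.8 TPM (log2 -3.93 ± 0.18, limma adjusted p = 4.36e-13) and Plin2 to 73.6 ± 0.657 from 89.6 ± 3.71 TPM (log2 -0.28 ± 0.06, limma adjusted p = 0.000569). Of 16161 genes, 3019 were higher and 2030 lower past limma's test. Also higher were Pla2g7, Mfap4, St8sia2, Ntrk2, Aldoc and Bmp6 (2.29 to 3.11 log2), and lower Hao1, Il33, Areg, Trf, Nr4a1, Spp1 and Timp1 (-2.18 to -2.89 log2). Of 14 homeostasis genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone). Their median was 1.20 log2 (camera adjusted p = 2.33e-12, adjusted p = 0.0162 with an estimated correlation), with Mlc1 at 1.72 and Glul at 1.14. Of 26 cholesterol synthesis genes, 21 rose, 1 fell and 4 did not pass (21 and 1 adjusted over the list alone). Their median was 0.67 log2 (camera adjusted p = 6.57e-10, adjusted p = 0.00952 with an estimated correlation), with Sqle at 1.23 and Nsdhl at 0.93, and the one that fell was Ebp. Of 28 cell cycle genes, 0 rose, 27 fell and 1 did not pass (0 and 27 adjusted over the list alone). Their median was -0.69 log2 (camera adjusted p = 5.24e-18, adjusted p = 0.0039 with an estimated correlation), with Ccnb2 at -0.91 and Birc5 at -0.84. Of 18 activated phagocyte genes, 1 rose, 11 fell and 6 did not pass (2 and 12 adjusted over the list alone). Their median was -0.74 log2 (camera adjusted p = 2.9e-07, adjusted p = 0.00154 with an estimated correlation), with Axl at -0.85 and Gpnmb at -1.24, and the one that rose was Ctsb, chosen, like Ebp, after its values were seen. Of 9 choroid plexus and ependyma markers 8 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 1.18 log2 (camera adjusted p = 4.74e-07, adjusted p = 0.00806 with an estimated correlation). Of 7 oligodendrocyte precursor markers 4 rose and 1 fell (4 and 2 adjusted over the list alone), with a median of 0.69 log2 (camera adjusted p = 0.0358, adjusted p = 0.20 with an estimated correlation). Adora2a was at 0.26 ± 0.184 against 0.533 ± 0.18 TPM and did not pass limma's test (adjusted p = 0.126).

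Microglial markers, with C1q complement genes, and genes of fatty acid oxidation were higher in Apoe knockout astrocyte cultures given oleic acid. Apoe was at 68.2, 72.9 and 71.4 TPM with oleic acid and 40.4, 47.1 and 43.5 TPM untreated (log2 0.69 ± 0.10, limma adjusted p = 1.42e-05). Plin2 rose to 181 ± 6.79 from 89.6 ± 3.71 TPM (n = 3 each, log2 1.00 ± 0.06, limma adjusted p = 1.79e-10) and the complement gene C1qa to 252 ± 24.9 from 69 ± 8.55 TPM (log2 1.85 ± 0.11, limma adjusted p = 5.11e-10), while Inhba, an activin subunit, fell to 10.7 ± 1.24 from 47.7 ± 3.39 TPM (log2 -2.06 ± 0.36, limma adjusted p = 0.000146). Of 16161 genes, 3502 were higher and 3247 lower past limma's test. Also higher were Cd52, C3, C1qb, C1qc, Tbc1d9, Mt1 and Txnip (1.54 to 2.05 log2), and lower Tnfrsf11b, Nr4a1, R3hdml, Nexn, Atrx, Hs6st2 and Prkg2 (-1.60 to -2.04 log2). Of 26 genes of fatty acid oxidation and PPAR targets, 23 rose, 1 fell and 2 did not pass (23 and 1 adjusted over the list alone). Their median was 0.50 log2 (camera adjusted p = 1.37e-11, adjusted p = 0.00181 with an estimated correlation), with Hadh at 0.69 and Acaa2 at 0.86, and the one that fell was Acadm, chosen after its values were seen. Of 19 microglial markers, 14 rose, 0 fell and 5 did not pass (14 and 0 adjusted over the list alone). Their median was 1.07 log2 (camera adjusted p = 6.14e-11, adjusted p = 0.00456 with an estimated correlation), with Cx3cr1 at 1.52 and Laptm5 at 1.40. Of 23 immediate early genes, 0 rose, 16 fell and 7 did not pass (0 and 16 adjusted over the list alone). Their median was -0.68 log2 (camera adjusted p = 1.38e-07, adjusted p = 0.151 with an estimated correlation), with Btg2 at -0.93 and Npas4 at -1.46. Gfap rose to 104 ± 3.99 from 70.8 ± 0.648 TPM (limma adjusted p = 2.1e-05), and Adora2a, at 0.507 ± 0.0777 against 0.533 ± 0.18 TPM, did not pass limma's test (adjusted p = 0.924). Mitochondrial genes took 4.04% to 4.53% of TPM against 6.41% to 6.64%.

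Genes of the integrated stress response were higher and Gfap and Aqp4 lower in Apoe knockout astrocytes given palmitic acid. Apoe was at 7.53, 7.66 and 5.36 TPM with palmitic acid and 40.4, 47.1 and 43.5 TPM untreated (log2 -2.52 ± 0.10, limma adjusted p = 1.18e-15). Ddit3 rose to 956 ± 82 from 38.4 ± 1.31 TPM (n = 3 each, log2 4.60 ± 0.08, limma adjusted p = 6.58e-21), Plin2 to 401 ± 23 from 89.6 ± 3.71 TPM (log2 2.15 ± 0.06, limma adjusted p = 2.52e-18) and Hspa1b, a heat shock gene whose near-identical copy Hspa1a can share its reads, to 505 ± 38.9 from 11.5 ± 0.668 TPM. Gfap fell to 2.36 ± 0.25 from 70.8 ± 0.648 TPM (log2 -4.42 ± 0.08, limma adjusted p = 6.58e-21), and Aqp4, the astrocyte water channel, to 3.11 ± 1.0 from 134 ± 4.8 TPM. Of 16161 genes, 3222 were higher and 8946 lower past limma's test, and 5731 and 6295 with median-ratio scaling, which moved the median log2 fold change of all genes from -0.47 to -0.09. Also higher were Hspa1a, Trib3, Derl3, Chac1 and Atf3 (4.32 to 5.11 log2) and Try5, a trypsin gene whose family can share its reads, and lower Akr1c14, Ogn, Cnn1, Fabp7, Ctnnal1 and Atp1b2 (-4.33 to -4.74 log2). Of 23 genes of the integrated stress and unfolded protein responses, 22 rose and 1 fell (22 and 1 adjusted over the list alone). Their median was 2.20 log2 (camera adjusted p = 6.1e-21, adjusted p = 0.000116 with an estimated correlation), with Herpud1 at 3.50 and Ppp1r15a at 3.78, and the one that fell was Vldlr. Of 26 cholesterol synthesis genes, 21 rose, 1 fell and 4 did not pass (21 and 1 adjusted over the list alone). Their median was 1.20 log2 (camera adjusted p = 2.55e-15, adjusted p = 0.00202 with an estimated correlation), with Fdps at 3.41 and Fdft1 at 1.99, and the one that fell was Ggps1, chosen, like Vldlr, after its values were seen. Of 28 cell cycle genes, 0 rose and 28 fell (0 and 28 adjusted over the list alone). Their median was -3.10 log2 (camera adjusted p = 1.06e-13, adjusted p = 0.0112 with an estimated correlation), with Ccnb2 at -3.20 and Mcm6 at -2.59. Of 19 microglial markers, 0 rose and 19 fell (0 and 19 adjusted over the list alone). Their median was -2.62 log2 (camera adjusted p = 1.66e-06, adjusted p = 0.0319 with an estimated correlation), with Ctss at -3.55 and Cx3cr1 at -2.89. Adora2a rose to 1.34 ± 0.060 from 0.533 ± 0.18 TPM (limma adjusted p = 0.000388). The palmitic acid libraries had 12057 to 12915 genes at 1 TPM or more against 14422 to 14488 untreated, 1.51%, 2.94% and 2.58% of TPM from mitochondrial genes against 6.41% to 6.64%, and Ddx3y at 1.86, 15.7 and 9.91 TPM. Library 1 stood apart, with SDs of log2 differences of 0.631 and 0.533 from the others and 0.376 between those, and without it there were 11442 calls.

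Whether a treatment's change differed between genotypes was tested as the change in Apoe knockout minus the change in wild-type astrocytes (n = 3 in each group), which carries the Ddx3y and En2 differences between cultures. For medium from neurons, Gfap had a log2 difference of 2.02 (SE 0.11, limma adjusted p = 4.9e-11) and Il33 of -2.57 (SE 0.19, limma adjusted p = 2.38e-09). Of 16161 genes, 1872 differences were higher and 1123 lower past limma's test. Of 14 astrocyte homeostasis genes, 12 were higher, 0 were lower and 2 did not pass (13 and 0 adjusted over the list alone). Their median was 1.06 log2 (camera adjusted p = 6.78e-13, adjusted p = 0.0136 with an estimated correlation). Of 26 genes of cholesterol synthesis, 20 were higher, 1 was lower and 5 did not pass (21 and 1 adjusted over the list alone). Their median was 0.74 log2 (camera adjusted p = 5.36e-12, adjusted p = 0.00385 with an estimated correlation). The lower one was Ebp, chosen after its values were seen. Of 28 genes of the cell cycle, 0 were higher, 27 were lower and 1 did not pass (0 and 27 adjusted over the list alone). Their median was -0.81 log2 (camera adjusted p = 1.98e-22, adjusted p = 0.00242 with an estimated correlation). Plin2 and Adora2a did not pass limma's test (differences -0.19 and -0.27, adjusted p = 0.121 and 0.399).

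For oleic acid, Nr4a1 had a log2 difference of -6.46 (SE 0.21, limma adjusted p = 3.04e-15) and Col3a1 of 4.76 (SE 0.24, limma adjusted p = 2.16e-12). Of 16161 genes, 2225 differences were higher and 2554 lower past limma's test, and of 36 lists 18 and 5 past camera's. Of 23 immediate early genes, 3 were higher, 17 were lower and 3 did not pass (3 and 17 adjusted over the list alone). Their median was -1.63 log2 (camera adjusted p = 1.84e-10, adjusted p = 0.0596 with an estimated correlation). The higher ones were Bdnf, Dusp6 and Nptx2, chosen after their values were seen. Of 14 astrocyte homeostasis genes, 12 were higher, 0 were lower and 2 did not pass (12 and 0 adjusted over the list alone). Their median was 1.06 log2 (camera adjusted p = 1.84e-10, adjusted p = 0.0385 with an estimated correlation). Of 19 microglial markers, 14 were higher, 1 was lower and 4 did not pass (15 and 1 adjusted over the list alone). Their median was 0.67 log2 (camera adjusted p = 6.24e-06, adjusted p = 0.0466 with an estimated correlation). The lower one was Olfml3. Plin2, at -0.11, did not pass limma's test (adjusted p = 0.357).

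For palmitic acid, Fdps, of cholesterol synthesis, had a log2 difference between genotypes of 3.08 (SE 0.16, limma adjusted p = 8e-13), C1qa of -4.76 (SE 0.16, limma adjusted p = 1.13e-15) and Plin2 of 0.21 (SE 0.08, limma adjusted p = 0.0331). Of 16161 genes, 2319 differences were higher and 6985 lower past limma's test, and 4630 and 4271 with median-ratio scaling, which moved the median of all genes from -0.35 to 0.02. Of 26 genes of cholesterol synthesis, 24 were higher, 1 was lower and 1 did not pass (24 and 1 adjusted over the list alone). Their median was 1.84 log2 (camera adjusted p = 2e-27, adjusted p = 0.000111 with an estimated correlation). Of 19 microglial markers, 1 was higher, 17 were lower and 1 did not pass (1 and 17 adjusted over the list alone). Their median was -3.57 log2 (camera adjusted p = 4.06e-09, adjusted p = 0.00877 with an estimated correlation). Ggps1, lower, and Tmem119, higher, were the exceptions, chosen after their values were seen. Of 28 cell cycle genes, 0 were higher and 28 were lower (0 and 28 adjusted over the list alone). Their median was -2.81 log2 (camera adjusted p = 3.66e-20, adjusted p = 0.00156 with an estimated correlation).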

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

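The tests of the third untreated library, of the astrocyte preparations and of the odds of a call near Apoe were chosen only after the result was seen.

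In the KA libraries of the second cohort, KA 4 lay far from the other 3 for Myh11, at 3.457 TPM against 4.271 to 4.35, and for Egr1, at 69.41 TPM against 29.06 to 34.51. These were 2 of 61 genes tested, and chance gives about 1 in 20.

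Treatments' changes differed between knockout and wild-type cultures by limma's interaction test, which cannot tell genotype from culture source. For medium from neurons it passed for 2995 genes, with log2 differences of Eln 3.21, Pla2g7 2.99, Mfap4 2.87, Cdkn1c 2.83, Rln1 2.73, Spon1 2.64, St8sia2 2.44, Fam107a 2.35, Hao1 -3.70, Il33 -2.57, Plaur -2.11, Rarres1 -2.06, Spp1 -2.04, Trf -2.00, Rgs16 -1.98, Fgf7 -1.93, Apoe 1.40 and Gfap 2.02. For oleic acid it passed for 4779 genes, with differences of Col3a1 4.76, Actg2 3.74, Itih3 3.64, Pla2g7 3.48, Scrg1 3.42, Itm2a 3.36, Serpina3n 3.25, Fxyd6 2.95, Nr4a1 -6.46, Wif1 -5.80, En2 -5.35, Cnpy1 -5.04, Foxa2 -4.44, Il33 -4.38, Foxa1 -4.31, Medag -3.93, Apoe 1.22, Adora2a -1.03 and Gfap 1.59. For palmitic acid it passed for 9304 genes, with differences of Igf2 3.71, Insig1 3.16, Fdps 3.08, Mvd 3.01, Scd2 2.83, Aplp1 2.57, Spp1 -5.58, Rgs8 -5.37, Ncan -4.90, Vgf -4.86, mt-Co2 -4.85, C1qa -4.76, Cd52 -4.68, Crabp1 -4.63, Apoe -1.50, Gfap -2.35 and Plin2 0.21. Of 100 splits of the libraries, the real one included, 11, 4 and 1 gave as many genes for medium, oleic and palmitic acid (highest other 5452, 7708 and 8204). These splits put libraries of both genotypes, which differed in 7258 genes untreated, in 1 group, so the splits decide nothing about chance.

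For comparisons of 3 against 3 libraries the 10 splits cannot give a share under 0.1, and the real split alone gave as many genes. The real and highest other counts were 28 and 1 in first-cohort KA, 571 and 2 in CNO, 6 and 3 in medium from neurons, 243 and 1 in knockout neuronal medium, 229 and 7 between the media, 9669 and 1 in oleic acid, 9668 and 1 in palmitic acid, 9406 and 2 between the fatty acids, and 7258 and 0 between genotypes. In knockout astrocytes they were 5049 and 1 with medium from neurons, 6749 and 0 with oleic acid and 12168 and 1 with palmitic acid. Of 35 splits, the real one included, 2 gave as many genes in the second KA cohort (13, highest other 18). The libraries labelled A2aR knockdown gave 2 too (9, highest other 13), so chance is not excluded in either. In Apoe knockout with KA 1 did (26, highest other 3), the fewest possible.

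In the first KA cohort, untreated 3 stood apart. The tables argue against a KA library under an untreated label, since its median deviation was -0.0385 of the KA difference for microglial markers and -0.103 for pan-reactive astrocyte genes. A bias by transcript length may account for it: its deviation correlated across genes with exon length at Spearman -0.544, against -0.031 for the difference between untreated 1 and 2. Neither its cause nor a biological explanation was tested.

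Wild-type astrocyte cultures with oleic or palmitic acid differed from untreated ones in Y-linked genes and En2. The median log2 difference of the Y-linked genes was -2.52 with oleic and -1.87 with palmitic acid, and their median varied 3.11 times as much between as within the 9 groups. In Apoe knockout cultures it was lower with the fatty acids too, at 3.58 ± 0.06 with oleic and 2.65 ± 1.01 with palmitic acid against 4.43 ± 0.06 untreated (log2, n = 3 each). Y-linked values cannot tell cultures of 1 preparation split over the treatments from separate preparations. Both bounds set assumed that the fatty acids do not lower Y-linked genes, and such an effect stays open. En2 was not tested for this.

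Genes near Apoe were common among the calls of Apoe knockout with KA against KA. Within 20 Mb of Apoe 7 of 580 tested genes were called (Nudt19, Kirrel2, Sbsn, Gpatch1, Gm42372, Gm45104 and Gm45844) against 18 of 22737 elsewhere, an odds ratio of 15.4 (Fisher's exact test, two-sided, p = 1.85e-06). DNA of another strain carried along with the targeted allele may account for this and stays open. In untreated astrocytes 1 of 5 such genes tested, Gm42372, passed in the same direction. Cell types differ, so a difference shared by both knockouts stays open.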

How the results depend on the processing

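The removal of the transcript length trend and of X and Y genes, limma on TPM in the second cohort, the lists without untreated 3, and the list tests with a block in CNO were chosen only after the result was seen. Single named genes kept their side of the threshold in 7464 results under an alternative, 509 were no longer past it and 58 became so. Direction was compared only where a gene passed in either setting, and there 0 changed it. The cause of the changes was not tested, but a stricter threshold gives fewer calls by construction.

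Counts moved by over 1.5 times as follows. Without a filter on low values, they were 2 in first-cohort KA, 197 in CNO and 30 in medium from neurons on wild-type astrocytes. With a pseudocount of 0.1 they were 44 in first-cohort KA, 3 in medium from neurons and 128 between the media. Median-ratio scaling gave 2 in medium from neurons, 159 in knockout neuronal medium and 141 between the media. With DESeq2 they were 155 in second-cohort KA, 327 in Apoe knockout with KA and 249 in the libraries labelled A2aR knockdown. Fitting only the groups compared gave 11 in Apoe knockout with KA, 10 of them shared. It gave 1 in the libraries labelled A2aR knockdown and 1 in medium from neurons, both with 0 shared. Removing the length trend gave 91 in first-cohort KA, and leaving out X and Y genes gave 4 in second-cohort KA.

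With a 2-fold threshold, counts were 348 in CNO, 0 in medium from neurons (limma, 1031 at an unadjusted p under 0.05), 50 in knockout neuronal medium, 55 between the media, 2063 in oleic acid, 2724 in palmitic acid, 2361 between the fatty acids and 1712 between genotypes. In knockout astrocytes they were 823 with medium from neurons, 477 with oleic acid and 5279 with palmitic acid, and for the interactions 768, 1293 and 3947.

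With a replicate block, the count was 928 in CNO, where numbers pair libraries and 560 genes were shared with the fit without it. It was 2 in first-cohort KA and 5 in Apoe knockout with KA, where correlations by number were -0.081 to -0.011 and -0.019 to -0.014 and 0 of 3 libraries went best with their own number. The libraries labelled A2aR knockdown, numbered 4 to 6, share only 1 number with KA and could not be paired.

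With an estimated correlation the lists past camera's test numbered 0 in first-cohort KA (21 with the preset one), 0 in second-cohort KA (14), 0 in Apoe knockout with KA (16), 0 in the libraries labelled A2aR knockdown (12), 0 in CNO (18), 1 in medium from neurons, 3 in knockout neuronal medium, 0 between the media (13), 3 in oleic acid, 4 in palmitic acid, 4 between the fatty acids, 3 between genotypes, and in knockout astrocytes 7 with medium from neurons, 3 with oleic acid and 5 with palmitic acid. For the interactions they were 7, 5 and 7.

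For first-cohort KA genes in the other brain tables, lists without untreated 3 gave camera p = 0.153 in second-cohort KA, 0.467 in Apoe knockout with KA, 0.0152 in the libraries labelled A2aR knockdown and, for the lower list in CNO, 0.0177, and the estimated correlation gave 0.0516 for the higher list in CNO (limma's camera, unadjusted).

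Leaving out single libraries gave 0 to 352 calls in first-cohort KA, 9 to 20 in second-cohort KA, 15 to 27 in Apoe knockout with KA, 0 to 12 in the libraries labelled A2aR knockdown, 167 to 591 in CNO, 0 to 11 in medium from neurons, 117 to 154 in knockout neuronal medium and 105 to 165 between the media. Counts of 0 came without untreated 2, KA 1 or KA 2 in first-cohort KA (limma, 1929, 1046 and 883 at an unadjusted p under 0.05), without labelled library 5 in the libraries labelled A2aR knockdown (edgeR, 2285), and without untreated 2, treated 1 or treated 3 in medium from neurons (limma, 864, 758 and 979). Beyond the 3 counts given above the block moved no count by over 1.5 times. TPM tables keep no depth, so low genes there cannot be judged by counting error.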

Other observations

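The values here, except the counts of calls without the libraries titled mix, were chosen after the result was seen, and none tests a hypothesis.

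Ttr, made by choroid plexus, was at 1745 ± 399 TPM in first-cohort KA and 525 ± 480 TPM in untreated, and at 660, 0.99 and 686 TPM in the CNO libraries.

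In knockout astrocytes with palmitic acid, library 3, titled mix, lay between the other pair in 993 of 1086 genes (91.4%), among genes over 2-fold apart between that pair. In the other groups it was 36.5% to 68.5%, the lowest being untreated knockout, whose library 3 is also titled mix (35 of 96 genes). Without both, calls of palmitic acid in knockout astrocytes numbered 11289, against 12168 with them.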
